A study of Mus musculus with 12 samples.

How the data were processed

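RNA was measured in laser-captured external granule layer of the central cerebellar lobules of C57BL/6 mice at postnatal day 6. Per the labels' protocols, RNA was extracted with a column kit for small amounts that removes genomic DNA, RNA integrity was checked on a BioAnalyzer, and libraries were made with a NEBNext Ultra kit for Illumina that does not mark strand. The deposited values are whole-number read counts per gene, 1 table per library, in the output format of HTSeq. Per the submitters' processing notes the tools were cutadapt 1.16, STAR 2.5.3a, HTSeq 0.6.1 and DESeq2, whose version is not given, with genome build mm10; their settings, the annotation release and the strand setting of the counting are not given in the sources used here. The deposited counts are not normalized.

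Each table held 53379 gene rows and 5 summary rows. The summary rows were left out of library sizes and tests. Alignments to several places made up 64.4% to 67.6% of all records, and of the uniquely placed reads 10.8% to 14.7% fell in no gene and 6.81% to 8.13% were ambiguous between genes. Values of genes with near-identical copies, such as Hba-a1 and Hba-a2, ribosomal protein genes with processed pseudogenes, and mitochondrial genes with nuclear copies, are uncertain for that reason. Of the gene identifiers, 53274 were matched to symbols and to positions in GENCODE M21 (GRCm38, the build also called mm10). Of the 109 genes named by rule, 43 overlap an annotated gene on the opposite strand, whose reads cannot be told apart from theirs by strand.

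Groups and library numbers were taken from the titles. The names of the deposited tables repeat the title's group and number and add a second number in another order, which the labels do not explain and which was not used. KO2, whose genotype tag says wild type, was kept as knockout by its title, and counting it as wild type was an alternative. WT2 and KO4, marked as outliers in their descriptions, were left out of the comparison, which left 5 against 5 libraries, and fits to all 12 libraries were an alternative. Within a group, the counts of all 30 pairs of libraries differed by far more than sampling noise (chi-square per degree of freedom 6.15 to 85.3), so no 2 tables were taken for the same library sequenced again; this does not show that they came from separate animals.

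Genes were filtered with filterByExpr (minimum count 10), which left 13442, scaled with TMM factors and compared by edgeR's quasi-likelihood test with robust dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Means and SDs are of TMM-scaled CPM, the count per 1e+06 of a library's counts in filtered genes times its TMM factor, with filter and factors taken over all 12 libraries. Values of single genes and library measures were also compared by two-sided exact permutation tests, on log2 of CPM plus 1 for genes. The 24 gene lists, fixed before the data were examined, cover proliferation, the granule lineage, signalling, and cell types that the layer could hold. They were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and a list needed 3 measured genes. Neither called list passed with an estimated correlation or with fry. Some genes belong to more than one list.

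Also fixed before the data were examined were the comparison, the alternative settings and the rule for named genes. The rule takes Skil, the genes with the smallest p in each direction (up to 12 that pass, or the 5 smallest where fewer than 5 pass), up to 4 members of each list with the smallest p, and 14 chosen genes of the precursor and cell cycle programme; genes with provisional names may be passed over. These settings were DESeq2 1.42.0, limma voom with sample quality weights on 12 libraries, RLE factors or library size alone, no filter beyond a count of 1, a filter of 1 CPM in 5 libraries, a Y-linked covariate for sex, 1 surrogate variable (sva 3.50.0), the replicate number as a block, and each library left out in turn. Added after seeing the data were a correction for GC content, in which each library's trend of log2 CPM on transcript GC content (a spline with 5 degrees of freedom) entered as an offset, and fits that left out only WT2 or only KO4. Genes per chromosome were counted at an unadjusted p under 0.01. The results of some genes were left out at the end and are not reported here, nor are they among the groups of values in flagged.md.

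The procedure was tested on simulated counts for the 5 against 5 comparison, drawn from the real means and library sizes with 200 genes changed. In a fit of 13233 genes it recovered 46.3% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, and 5.73% of its calls were unchanged genes. A simulated list shifted by 0.5 log2 units was found and 0 of 23 unshifted lists were called. All genes were drawn independently, whereas the correlation estimated between the real mitochondrial genes was 0.872. The simulation thus cannot show how often a list of correlated genes is called by chance. With a simulated GC trend, the correction lowered the number of unchanged genes called from 539 to 14, and 147 of the 200 changed genes were recovered against 149 without it.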

Results

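RNA was sequenced from the external granule layer of the cerebellum of mice at postnatal day 6, the layer in which granule neuron precursors divide before they become neurons. The layer was cut out by laser capture from mice with a conditional knockout of SnoN, a transcriptional regulator encoded by Skil that binds SMAD proteins of the TGF-beta pathway, and from control littermates. There were 6 wild-type libraries, numbered 1, 2, 3, 5, 6 and 7, and 6 knockout libraries, numbered 2, 3, 4, 5, 6 and 8, written here as WT1 or KO2. The submitters marked WT2 and KO4 as outliers by a robust principal component analysis, so the comparison used the other 5 wild-type and 5 knockout libraries, and for some results the values of the marked libraries, or fits that include them, are given beside it. The deposited gene counts summed to between 7520076 in WT6 and 15083086 in KO8. Between 18216 and 20037 genes per library had at least 1 count. The labels do not say that each library came from a separate animal, so p-values measure the spread between libraries, which may be partly technical. The study addressed whether SnoN acts on the proliferation of granule neuron precursors in the postnatal brain, and the question for these libraries is which transcripts differ in the precursor layer when SnoN is removed.

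Skil itself (ENSMUSG00000027660.16, chromosome 3, 31095058 to 31122577 in GRCm38, plus strand) was lower in the knockout. Its mean was 49.9 ± 7.98 CPM (TMM-scaled counts per 1e+06; SD, n = 5) in wild type and 30.7 ± 6.39 CPM (SD, n = 5) in knockout, a log2 fold change of -0.70 with a standard error of 0.15. Each of the 5 knockout libraries lay below each of the 5 wild-type libraries, with a two-sided exact permutation p of 0.00794, the smallest that 5 against 5 libraries can give. Wild-type values were 47.5 CPM in WT1, 57.8 in WT3, 57.3 in WT5, 38.5 in WT6 and 48.5 in WT7, and knockout values were 36.1 CPM in KO2, 36.7 in KO3, 20.9 in KO5, 30.1 in KO6 and 29.9 in KO8. The 2 marked libraries lay further apart, at 76.5 CPM in WT2 and 14.0 CPM in KO4. The genotype tag of KO2 says wild type although its title says knockout; its Skil value of 36.1 CPM was below the lowest wild-type value of 38.5 CPM. In edgeR's quasi-likelihood test the unadjusted p was 2.1e-04. The Benjamini-Hochberg adjusted p over all 13442 genes tested was 0.124, so Skil did not pass at 0.05 across the transcriptome. Without KO5, the lowest of the 5 knockout values, the log2 fold change shrank to -0.59. The adjusted p was then 0.00275, in a fit in which 3102 genes passed. With the marked libraries included the log2 fold change was -0.96 (unadjusted p = 3.8e-04, adjusted p = 0.9985). With each library's trend on GC content removed, the log2 fold change was -0.95 with an adjusted p of 4.5e-04. Over all alternative settings the adjusted p ranged from 3.3e-05 to 1. The counts cover the whole gene and the labels do not name the deleted part, so reads from exons outside the deletion are included.

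Across the transcriptome, 3 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 2 higher and 1 lower in knockout. Trmt9b (chromosome 8, 36457548 to 36516570), a tRNA methyltransferase homologue, rose from 1.13 ± 0.406 CPM to 5.14 ± 1.09 CPM (SD, n = 5 each), a log2 fold change of 2.18 (SE 0.30, adjusted p = 0.0124). Its lowest wild-type count was 6 reads. Fut10 (chromosome 8, 31187331 to 31261738), a fucosyltransferase of the secretory pathway, fell from 38.2 ± 4.25 CPM to 22.1 ± 1.43 CPM, a log2 fold change of -0.79 (SE 0.12, adjusted p = 0.0160). Cdh7 (chromosome 1, 109982431 to 110140157), a cell adhesion molecule of the cadherin family, rose from 26.7 ± 2.96 CPM to 50.7 ± 10.8 CPM, a log2 fold change of 0.92 (SE 0.14, adjusted p = 0.02). For Trmt9b and Cdh7 all 5 knockout libraries lay above all 5 wild-type libraries, and for Fut10 all 5 lay below. With the marked libraries included, Trmt9b passed (log2 fold change 2.19, adjusted p = 0.00330), and Fut10 (-0.72, adjusted p = 0.115) and Cdh7 (0.70, adjusted p = 0.998; 49.4 CPM in WT2 and 43.1 in KO4, the opposite order) did not. Trmt9b and Fut10 both lie on chromosome 8, on which more genes differed than on other chromosomes in the fit to 12 libraries. Fut10 overlaps an annotated pseudogene on the opposite strand. Trmt9b did not pass without WT7 (adjusted p = 0.0825) or without KO2 (0.0884), and Fut10 did not pass without WT6 (0.0729), WT7 (0.0968), KO2 (0.0884) or KO8 (0.0872). Cdh7 did not pass without WT1, WT5, WT6, WT7, KO2, KO3 or KO8, with adjusted p from 0.0872 to 0.143. Over all alternative settings the adjusted p reached 1 for each of these genes, and the direction did not change.

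**Figure D1:**
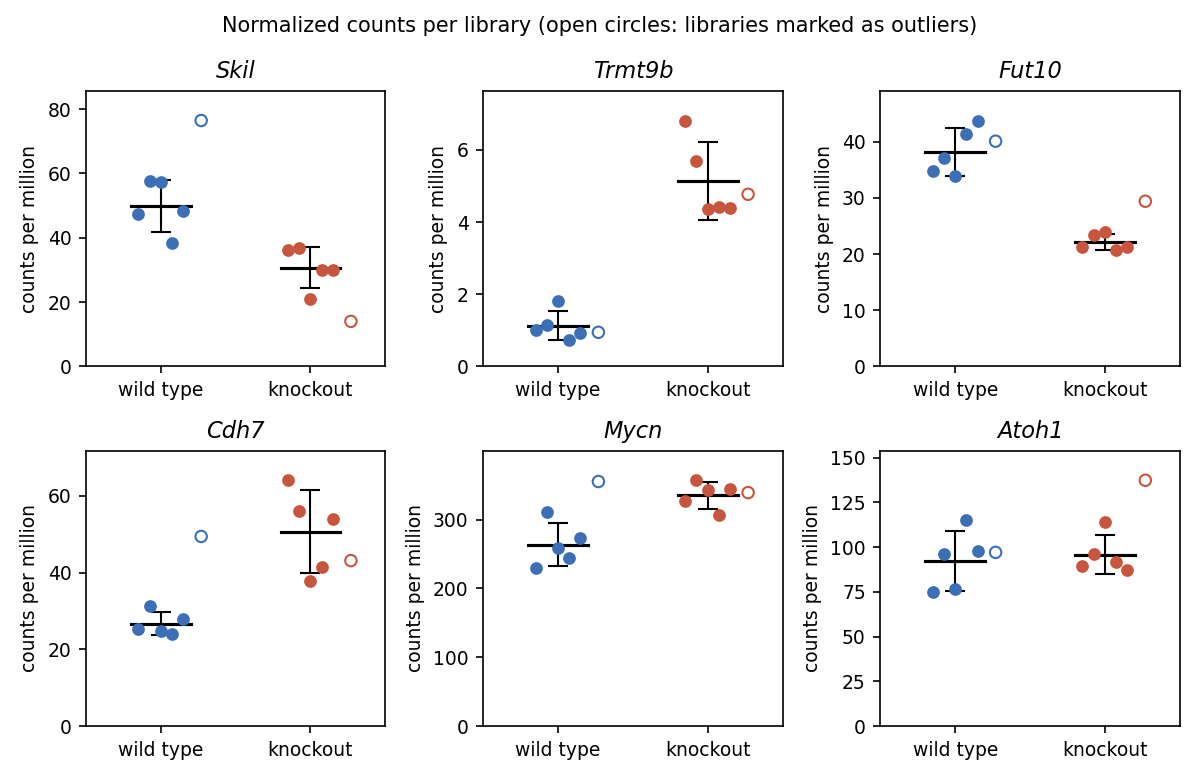
Normalized CPM (y axis) of 6 genes in each library, wild type in blue and knockout in red; filled points are the 5 libraries per group used in the comparison, lines and bars their mean and SD, and open circles the marked libraries WT2 and KO4. Skil and Fut10 were lower and Trmt9b and Cdh7 higher in all 5 knockout libraries, Mycn averaged 263 CPM in wild type and 335 CPM in knockout, and Atoh1 92.2 and 95.8 CPM.

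The genes next in rank had an adjusted p of 0.124 and did not pass. On the higher side was Nhsl1, related to a regulator of actin at the leading edge of cells (39.1 ± 2.52 CPM in wild type against 57.5 ± 5.67 CPM in knockout; SD, n = 5 each here and below). With it were the transcription factors Zbtb20 (75.5 ± 15.3 against 128 ± 25 CPM) and Nfia (532 ± 86.5 against 898 ± 204 CPM), the latter a regulator of granule neuron development. On the lower side were Wdr6, a WD repeat protein (142 ± 8.46 against 94.3 ± 14.4 CPM), and Cdc42bpb, a kinase that acts downstream of Cdc42 (22.4 ± 1.25 against 12.8 ± 3.62 CPM). Also lower were Pigb, an enzyme of GPI anchor synthesis (3.89 ± 0.927 against 1.53 ± 0.268 CPM), and Adcy8, a calcium-stimulated adenylyl cyclase (1.75 ± 0.408 against 0.424 ± 0.186 CPM). Nhsl1 passed once the GC trend was removed (log2 fold change 0.63, adjusted p = 0.0227), but not without KO2 in that fit (0.120). With the marked libraries included these 7 genes kept their direction and had an adjusted p of 0.998; Wdr6 was at 70.9 CPM in WT2 and 146 CPM in KO4, the opposite order, and its log2 fold change went from -0.588 to -0.337. Nhsl1, Nfia and Cdc42bpb also had the opposite order there. Zbtb20, Nfia and Wdr6 passed without KO6, with adjusted p of 0.0401, 0.0313 and 0.0489. All 7, Nhsl1 included, overlap annotated genes on the opposite strand. As the library kit does not mark strand, their reads cannot be told apart by strand from those of the overlapping genes.

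The proliferation lists were not called as different between the groups. Of 65 measured genes of G1/S and DNA replication, 7 were higher and 7 lower at an unadjusted p under 0.05, and the mean log2 fold change was -0.02 (camera adjusted p = 0.950). Of 71 measured genes of G2/M and mitosis, 14 were higher and 6 lower at that level, with a mean of -0.01 (adjusted p = 0.960). No gene of either list passed over all genes tested; adjusted over the list alone, 1 passed, the centriole duplication kinase Plk4 at 114 ± 11.0 CPM in wild type and 150 ± 10.8 CPM in knockout (SD, n = 5 each). Over the list alone 0 passed once the GC trend was removed, where edgeR's test gave Plk4 an unadjusted p of 0.0251. Mki67, the Ki-67 antigen of cycling cells, had 135 ± 9.20 CPM and 148 ± 25.6 CPM (log2 fold change 0.13, SE 0.11, adjusted p = 0.502). The cyclins Ccnd1 and Ccnd2 had log2 fold changes of -0.19 (SE 0.17, adjusted p = 0.533) and 0.01 (SE 0.11, adjusted p = 0.978). The cell cycle inhibitors Cdkn1a and Cdkn1b had -0.15 (SE 0.12) and 0.15 (SE 0.12), neither passing. Members with small unadjusted p went in both directions, and none of those named next passed. The spindle checkpoint kinase Ttk (39.0 against 54.2 CPM) and Casp8ap2 (104 against 142 CPM) had higher means in knockout. The chromatin assembly factor Chaf1a (25.6 against 16.3 CPM) and the replication helicase subunit Mcm5 (214 against 167 CPM) had lower means, as did the centromere chaperone Hjurp (94.3 against 66.0 CPM) and the condensin subunit Ncapd2 (80.8 against 51.2 CPM). In the marked libraries the order was opposite for Ccnd1, Cdkn1a, Plk4, Ttk, Casp8ap2, Chaf1a, Mcm5, Hjurp and Ncapd2. Including them moved the log2 fold changes of Plk4 from 0.399 to 0.236, Casp8ap2 from 0.451 to 0.179, Mcm5 from -0.357 to -0.191, Hjurp from -0.513 to -0.339, Ncapd2 from -0.659 to -0.308 and Ccnd1 from -0.185 to -0.084.

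Genes of granule neuron precursors and the Sonic hedgehog (Shh) pathway, the mitogenic signal from Purkinje cells to these precursors, had 42 measured members, 10 higher and 5 lower at an unadjusted p under 0.05. Their mean log2 fold change was 0.05 and the list was not called (camera adjusted p = 0.785). Adjusted over the list alone, 4 passed as higher and 3 as lower, and 6 and 1 with the GC trend removed. Mycn, a Shh target that drives precursor division, had 263 ± 31.4 CPM in wild type and 335 ± 19.4 CPM in knockout (SD, n = 5 each), a log2 fold change of 0.35 (SE 0.10, unadjusted p = 0.00258, adjusted p = 0.131). The transcription factor Sox9 had 53.2 ± 8.98 and 80.4 ± 11.1 CPM, and Nfix had 114 ± 13.7 and 72.6 ± 17.2 CPM; the marked libraries had the opposite order for Nfix, 29.0 CPM in WT2 and 126 CPM in KO4 (log2 fold change -0.655 without and -0.297 with them), and by less for Mycn (355 and 339 CPM) and Sox9 (84.7 and 82.3 CPM). Atoh1, the transcription factor that defines these precursors, had 92.2 ± 16.7 and 95.8 ± 10.8 CPM (log2 fold change 0.06, SE 0.13, adjusted p = 0.811). The Shh readouts Gli1 (-0.08, SE 0.15) and Ptch1 (0.31, SE 0.17) did not pass, with adjusted p of 0.802 and 0.287, and their signs turned with the marked libraries included (0.06 and -0.04). With the GC trend removed the list was called as higher (mean 0.10, adjusted p = 0.0392), but not with an estimated correlation (adjusted p = 0.637) or without KO2 (0.121). In all 12 libraries with the GC trend removed it was called as higher too (mean 0.084, camera adjusted p = 0.0139). An estimated correlation was not tried in that fit.

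Lists of granule neuron differentiation were not called either. Early differentiating granule neurons had 48 measured genes, 9 higher and 8 lower at an unadjusted p under 0.05, with a mean log2 fold change of 0.03 (camera adjusted p = 0.960); adjusted over the list alone, 2 passed as higher and 3 as lower (2 and 2 with the GC trend removed). Pax6, a transcription factor of the granule lineage, had 491 ± 54.9 CPM in wild type and 619 ± 81.4 CPM in knockout (log2 fold change 0.34, adjusted p = 0.141). Neurod1, a factor of neuronal differentiation, had 2582 ± 751 and 3628 ± 1110 CPM (0.49, adjusted p = 0.219). The adhesion molecule Cntn2 had 313 ± 32.8 and 242 ± 62.5 CPM (-0.37, adjusted p = 0.181). Of the members with the smallest p, the chromatin remodeller Chd7 had 179 against 245 CPM and the axon guidance receptor Dcc 14.1 against 8.57 CPM. Also among them, the cytoskeletal regulator Dpysl5 had 58.6 against 39.3 CPM and the adhesion molecule L1cam 20.1 against 14.1 CPM. None of these passed over all genes tested. Maturing granule neurons had 43 measured genes, 13 higher and 5 lower, with a mean of 0.12 (adjusted p = 0.487). Adjusted over the list alone, 8 passed as higher and 3 as lower, among them the synaptic vesicle gene Snap25 (47.9 against 69.3 CPM) and Rora (16.3 against 30.5 CPM) as higher and the glutamate receptor subunit Grin1 (4.84 against 2.64 CPM) and the synaptic organizer Cbln1 (271 against 213 CPM) as lower. Over the list alone 1 passed as higher and 0 as lower once the GC trend was removed. The marked libraries had the opposite order for Rora, which is also a Purkinje cell marker (57.2 CPM in WT2, 15.6 in KO4), and with them included its log2 fold change fell from 0.899 to 0.284 (unadjusted p = 0.444). The order was also opposite for Snap25, Dcc, Neurod1 (log2 fold change from 0.491 to 0.271 when they are included), Cntn2 (-0.367 to -0.229), Dpysl5 (-0.576 to -0.342), L1cam (-0.519 to -0.2), Grin1 (-0.862 to -0.482) and Cbln1 (-0.349 to -0.206). With the GC trend removed the maturing list was called as higher (mean 0.12, adjusted p = 0.0392). The adjusted p was 0.735 with an estimated correlation and 0.295 without KO2. In all 12 libraries with the GC trend removed the maturing list was called as higher too (mean 0.093, camera adjusted p = 0.0186). An estimated correlation was not tried there.

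For signalling, the SnoN and Ski family had 5 measured genes, with Skil lower and its relative Dach1 higher (265 ± 48.8 against 375 ± 97.9 CPM) when adjusted over the list alone (with the GC trend removed, 1 lower and 0 higher). For Dach1 the marked libraries had the opposite order (511 CPM in WT2, 221 in KO4), and its log2 fold change fell from 0.504 to 0.194 (unadjusted p = 0.416) with them included. Ski had a log2 fold change of -0.22 (SE 0.14, adjusted p = 0.345) and Skor1 0.40 (SE 0.34). The family's median and mean log2 fold changes were 0.12 and 0.02 while camera gave the direction as lower, with an adjusted p of 0.960. Of 28 measured TGF-beta/SMAD readouts, 3 were higher and 0 lower at an unadjusted p under 0.05 in edgeR's test and 2 passed adjusted over the list alone, the receptor Tgfbr1 (125 ± 12.3 against 177 ± 38.3 CPM) and Id4 (5.44 ± 1.24 against 9.43 ± 2.80 CPM). Neither passed over the list alone with the GC trend removed, and 0 of the list did in edgeR's test, where Tgfbr1 and Id4 had unadjusted p of 0.00333 and 0.0108. With the marked libraries included their log2 fold changes were 0.179 (unadjusted p = 0.417) and 0.485 (0.0810). The list mean was 0.10 (adjusted p = 0.800), and Smad7, the inhibitory SMAD that the pathway induces, had 14.5 ± 1.01 and 14.6 ± 0.713 CPM (SE of the log2 fold change 0.13, adjusted p = 0.990). Smad7 was at 6.97 CPM in WT2 and 20.7 CPM in KO4, and its log2 fold change went from 0.004 to 0.228 with them included. BMP and Notch targets had 20 measured genes, 3 higher and 0 lower, with a mean of 0.12 (adjusted p = 0.534). Adjusted over that list alone, 2 passed as higher, and 0 with the GC trend removed. The 2 were Id4, also a TGF-beta/SMAD readout, and the BMP receptor Bmpr1a (143 against 184 CPM). The Notch target Hes1 (3.76 against 5.75 CPM) did not pass over the list alone. The Wnt pathway had 23 measured genes, 5 higher and 3 lower, with a mean of 0.07 (adjusted p = 0.785). Adjusted over the list alone, 2 passed as higher and 0 as lower, and the same numbers with the GC trend removed. The Wnt inhibitor Wif1 had the smallest p of the list, at low levels of 0.996 against 2.73 CPM. The Wnt receptors Fzd1 and Fzd2 were at 12.4 against 17.1 CPM and 114 against 90.7 CPM. The p53 targets had 30 measured genes, 2 higher and 6 lower, with a mean of -0.07 (adjusted p = 0.566). The ectodysplasin receptor Eda2r was at 44.8 against 60.6 CPM and the apoptosis effector Bak1 at 16.2 against 11.7 CPM. Myc and nucleolar targets had 39 measured genes, 6 higher and 10 lower, with a mean of -0.08 (adjusted p = 0.487). Adjusted over the list alone, 4 were higher and 3 lower (1 and 1 with the GC trend removed), with the ribosome biogenesis gene Bop1 at 61.2 against 44.4 CPM and fibrillarin, Fbl, at 26.1 against 17.1 CPM. Opposite order in the marked libraries was also seen for Ski, Fzd2, Bak1, Fbl, Bmpr1a (log2 fold change from 0.361 to 0.168 when they are included), Fzd1 (0.462 to 0.307), Eda2r (0.439 to 0.096) and Bop1 (-0.464 to -0.281).

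Markers of other cells that the captured layer could hold were tested in the same way, and 1 such list was called. Purkinje cell markers rose as a list in knockout, with 21 of 24 measured genes at a positive log2 fold change, a mean of 0.30 and a camera adjusted p of 0.00223. With an inter-gene correlation estimated from the data the list's adjusted p was 0.974 (0.632 with the GC trend removed), and its unadjusted p was 0.0848. None passed over all genes tested; adjusted over the list alone, 5 passed as higher and 0 as lower, and 2 and 0 with the GC trend removed. The calcium-binding protein Calb1 had 90.2 ± 14.9 CPM in wild type and 138 ± 44.8 CPM in knockout, and the transcription factors Foxp1 and Foxp2 had 29.7 ± 4.69 against 40.8 ± 3.35 CPM and 15 ± 3.07 against 28.1 ± 14.2 CPM (SD, n = 5 each). The marked libraries had the opposite order for Calb1 (274 CPM in WT2, 70.7 in KO4) and Foxp2 (73.6 and 16.6), and by less for Foxp1 (47.9 and 47.4). With them included the log2 fold changes of Calb1 and Foxp2 fell from 0.609 to 0.066 (unadjusted p = 0.833) and from 0.902 to 0.089 (0.840). With the marked libraries included the mean was 0.16 and the adjusted p 0.0111. Over the other alternative settings of the fit the adjusted p ranged from 1.1e-04 to 0.0765.

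The remaining cell type lists were not called. Meninges and fibroblasts had 36 measured genes with a mean log2 fold change of 0.27, 3 higher and 2 lower at an unadjusted p under 0.05 (camera adjusted p = 0.284). The mesenchymal factor Tbx18 was at 15 against 23.3 CPM and the collagen gene Col6a2 at 6.36 against 3.14 CPM. The list passed without WT3 (adjusted p = 0.0136) or without KO8 (5.8e-04). It had an adjusted p of 0.974 with an estimated correlation in the 10 libraries and a mean of 0.057 in all 12 (camera direction lower, adjusted p = 0.997), and its adjusted p over all alternative settings ranged from 1.1e-04 to 0.997. Bergmann glia and astrocytes had 27 measured genes, 7 higher and 0 lower, with a mean of 0.10 (adjusted p = 0.487). Adjusted over that list alone, 2 passed as higher, Sox9 and Id4, which are also members of other lists. With the GC trend removed 2 passed over the list alone. The radial glial fatty acid binding protein Fabp7, at 513 against 688 CPM, was not among the genes that passed before the correction. For Fabp7 the marked libraries had the opposite order (1519 CPM in WT2, 501 in KO4), and its log2 fold change turned from 0.423 to -0.051 with them included. GABAergic interneurons had 15 measured genes, 4 higher and 1 lower, with a mean of 0.19 (adjusted p = 0.487). The GABA-synthesizing enzyme Gad1 was at 9.19 against 16.6 CPM and the vesicular transporter Slc32a1 at 6.09 against 3.70 CPM. Unipolar brush cells (7 measured genes, mean 0.07, adjusted p = 0.897), the oligodendrocyte lineage (14 genes, -0.10, 0.897), endothelial and mural cells (27 genes, -0.03, 0.910), microglia and macrophages (23 genes, 0.07, 0.960), blood (9 genes, -0.14, 0.800) and choroid plexus (4 genes, -0.17, 0.897) were not called. Myelin basic protein, Mbp, had 58.7 against 45.0 CPM, and the microglial complement gene C1qa 9.25 against 11.1 CPM. Like Fabp7, the genes Col6a2, Slc32a1, Tbx18 (44.0 CPM in WT2 and 10.6 in KO4, log2 fold change 0.099 with them included), Gad1 (log2 fold change from 0.848 to 0.275), Mbp (-0.385 to -0.207) and C1qa (0.26 to 0.061) had the opposite order in the marked libraries. With the GC trend removed, meninges and fibroblasts (adjusted p = 0.0392), Bergmann glia and astrocytes (0.0472) and ribosomal proteins (0.0402) were called as higher. With an estimated correlation in that fit their adjusted p values were 0.770, 0.637 and 0.770. Without KO2 in that fit they were 0.0507, 0.143 and 3.0e-04.

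Genes encoded by the mitochondrial genome rose as a list, with 8 of 8 measured genes at a positive log2 fold change, a mean of 0.65 and a camera adjusted p of 5.3e-04. The adjusted p was 0.974 with an estimated correlation, which was 0.872 between these genes. Adjusted over the list alone all 8 passed as higher, and over all genes none did; with the GC trend removed 0 passed over the list alone. The respiratory chain genes mt-Nd1 and mt-Cytb had 5087 ± 1188 against 7844 ± 2031 CPM and 3824 ± 771 against 6208 ± 2111 CPM (SD, n = 5 each). Mitochondrial genes took 2.21% ± 0.416 of the gene counts in wild type and 3.20% ± 0.806 in knockout (SD, n = 5 each; two-sided exact permutation p = 0.0556, Benjamini-Hochberg adjusted 0.148 over 7 library measures). The marked libraries had the opposite order, 4.88% in WT2 and 1.81% in KO4, and with them included the list mean was 0.18 and the adjusted p 0.147. With the GC trend removed the list mean was 0.24 (adjusted p = 0.0402; 0.637 with an estimated correlation). Of 81 measured ribosomal protein genes 12 were higher and 1 lower at an unadjusted p under 0.05, with a mean of 0.04 (adjusted p = 0.897). Immediate-early and stress genes had 22 measured members, 0 higher and 3 lower in edgeR's test, with a mean of 0.03 and a camera direction of lower (adjusted p = 0.910). Ddit4 was at 141 against 108 CPM and Jund at 125 against 99.5 CPM. Including the marked libraries, which had the opposite order for these 4 named genes, moved the log2 fold changes of mt-Cytb from 0.7 to 0.095 and mt-Nd1 down to 0.217, and those of Ddit4 from -0.387 to -0.219 and Jund from -0.326 to -0.103.

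**Figure D2:**
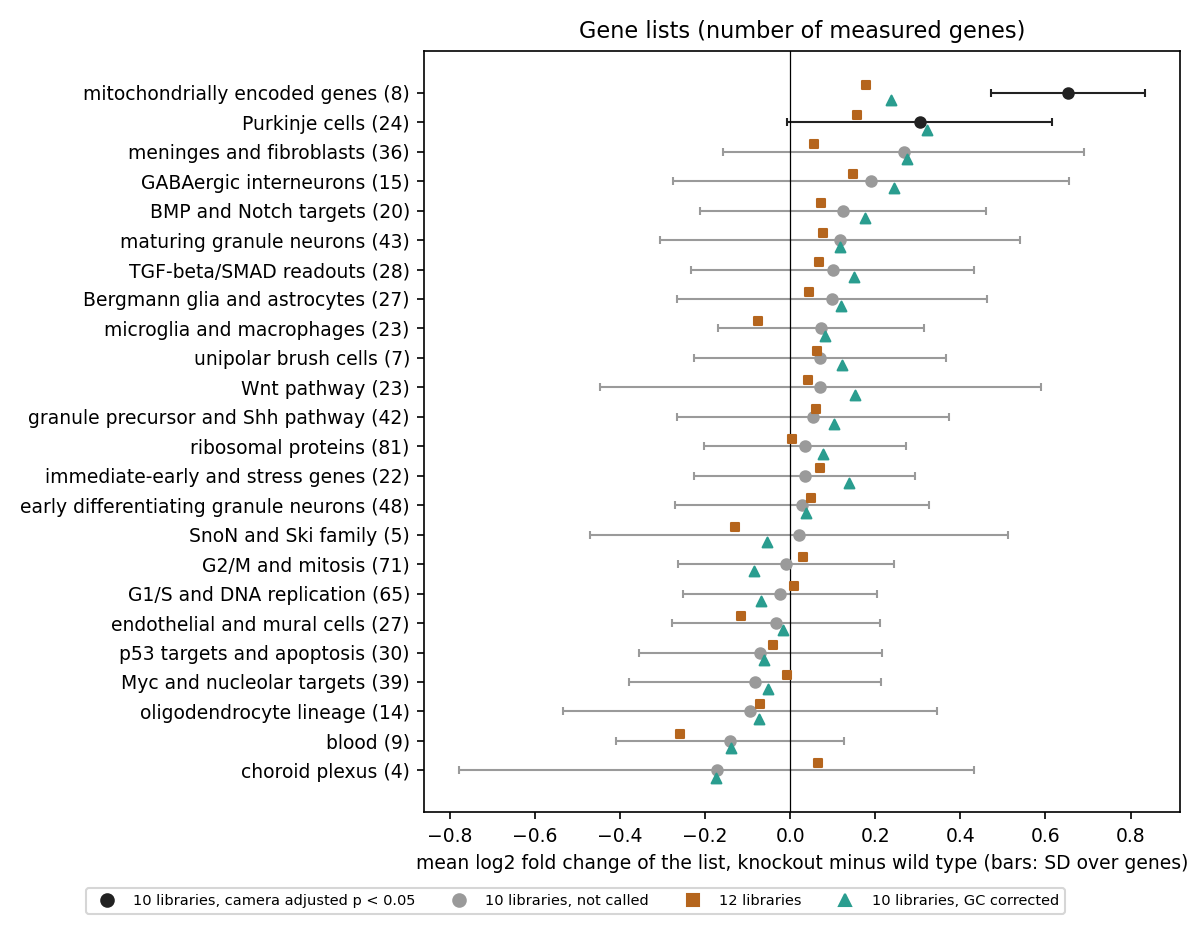
Mean log2 fold change, knockout minus wild type (x axis), of each of 24 gene lists, with the number of measured genes in brackets; circles are the 5 against 5 libraries with bars for the SD over genes, squares all 12 libraries and triangles the 5 against 5 libraries with the GC trend removed. Black circles mark the lists with a camera adjusted p under 0.05, mitochondrially encoded genes (mean 0.65) and Purkinje cells (mean 0.30), and the proliferation lists lie near 0.

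Many genes had a small unadjusted p, and the direction of their change went with their base composition. In the 10 libraries 2925 of the 13442 genes had an unadjusted p under 0.05 (21.8%, where 5% would be 672), 1585 higher and 1340 lower, a number for which chance could not be excluded. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.50 with the GC content of the gene's transcripts. The 387 genes with 38 to 40% GC had a median log2 fold change of 0.32, and the 769 genes with 58 to 60% GC had -0.19. Each library's slope of expression on GC content was 0.153 ± 0.0929 log2 units per 10 points of GC in wild type and -0.0911 ± 0.193 in knockout (SD, n = 5 each; two-sided exact permutation p = 0.0635), with KO5 at 0.204 inside the wild-type range. The marked libraries had the opposite order, -0.507 in WT2 and 0.199 in KO4, and with all 12 libraries 462 of 13318 genes had an unadjusted p under 0.05 and 1 passed after adjustment.

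The number of genes that passed depended on single libraries and on the test. Without KO5, 3102 genes passed, 1662 higher and 1440 lower. Without KO6, 6 passed, and without WT6 or KO8, 1 passed. Without WT7 or KO2, 0 passed in edgeR's test, with 2463 and 1942 genes at an unadjusted p under 0.05. DESeq2 on the 10 libraries gave 461 genes with an adjusted p under 0.05, 237 higher and 224 lower, of which 2 were among the 3 genes above. With KO2 counted as wild type by its genotype tag, 0 genes passed in edgeR's test and 756 had an unadjusted p under 0.05. With the GC trend removed, 5 genes passed, the 3 genes above with Skil and Nhsl1.

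**Figure D3:**
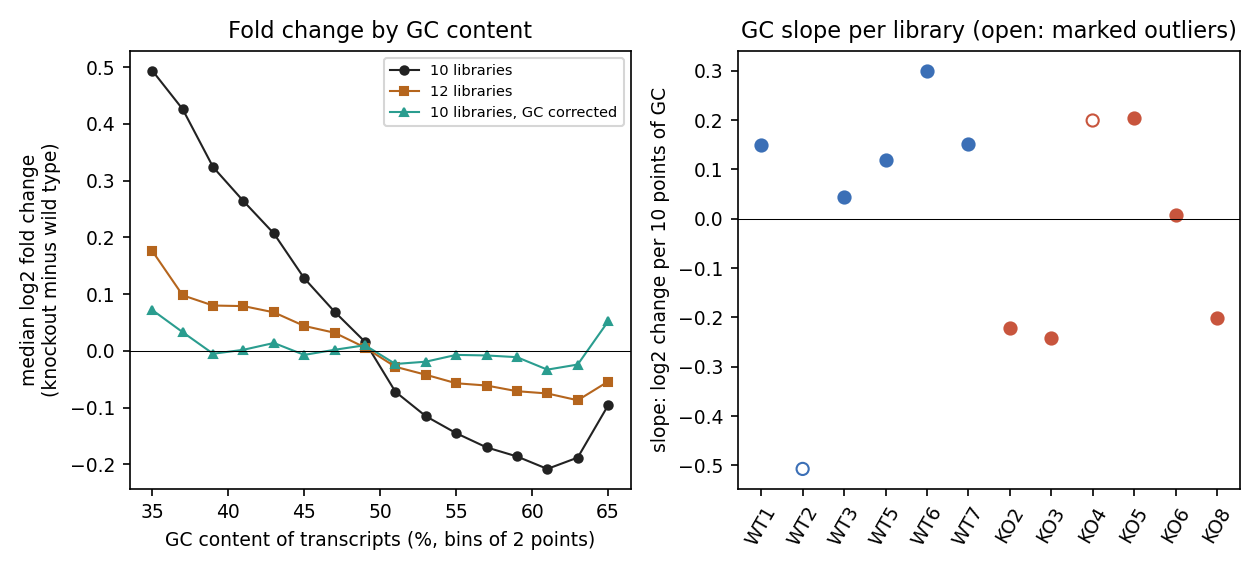
Left, median log2 fold change, knockout minus wild type (y axis), of genes in bins of 2 points of transcript GC content (x axis, percent), for 10 libraries, all 12 libraries, and 10 libraries with the GC trend removed. Right, the slope of expression on GC content (log2 units per 10 points) of each library, wild type in blue, knockout in red, with open circles for the marked libraries; WT2 at -0.507 and KO4 at 0.199 lie in the opposite order to the group means of 0.153 and -0.0911.

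Chromosome 8 held more differing genes than the other chromosomes when all 12 libraries were compared. Of its 701 tested genes, 12 had an unadjusted p under 0.01 (1.71%), against 56 of 12584 genes on the other autosomes and X (0.445%). Chance alone would give a share of 0.01, so part of the contrast comes from a low share elsewhere. The odds ratio was 3.9 with a 95% interval of 1.89 to 7.4 (two-sided Fisher's exact test p = 2.0e-04, Benjamini-Hochberg adjusted 0.00404 over the chromosomes). Of the 12, 5 were higher and 7 lower in knockout. Between 22 and 72 Mb in GRCm38 lay 10 of them, among them Nek3, Hgsnat, Fut10, Saraf, Dusp4, Trmt9b, Lpar2, Mau2 and Ocel1. These bounds enclose the outermost of the 10 genes, and the share of tested genes inside them is not given. None of the 10 lay between Trmt9b at 36.5 Mb and Lpar2 at 69.8 Mb, so they do not form 1 unbroken block. In Nek3, a kinase related to mitotic NIMA kinases, all 6 knockout libraries (5.55 to 8.66 CPM) lay above all 6 wild-type libraries (2.48 to 4.77 CPM). In Mau2, a cohesin loader subunit, the ranges were 64.6 to 71.1 CPM and 40.5 to 61.6 CPM. The genes named within these bounds other than Trmt9b and Fut10 were named after their values were seen. In the 10 libraries chromosome 8 had an odds ratio of 1.32 (adjusted p = 0.263), below the 1.52 on chromosome 10 (adjusted p = 0.0552), the highest there. Within 10 Mb of Skil on chromosome 3, 0 of 64 genes had p under 0.01 in 12 libraries and 3 had it in 10 libraries.

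**Figure D4:**
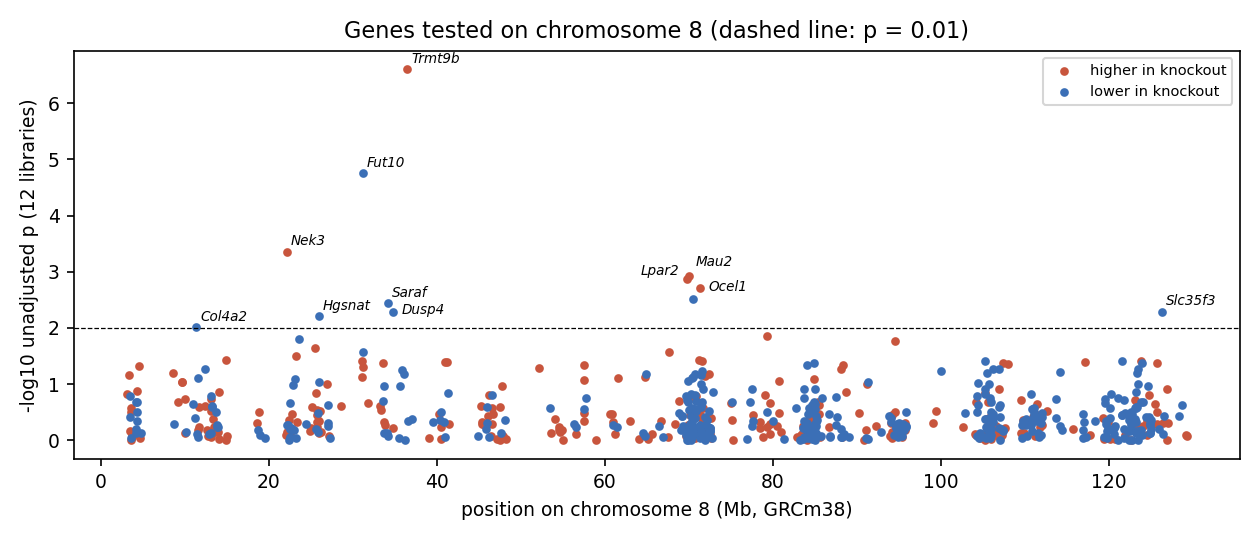
Minus log10 of the unadjusted edgeR p of each of the 701 tested genes of chromosome 8 over all 12 libraries (y axis) by position in Mb (x axis, GRCm38), red for genes higher and blue for genes lower in knockout, with a dashed line at 0.01. Of the 12 genes above the line, Trmt9b and Fut10 are at the top.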

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

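The GC correction, which the GC tests use, the test of Purkinje marker genes, the GC tests on the Purkinje list and on the number of differing genes, the count of lists over splits and the split test for chromosome 8 were chosen after the results were seen. Among 228 groups of values, 11 had a highest or lowest library whose gap to the nearest other library was large against the range of its group, and chance gives about 11.

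In wild type, WT3 stood apart at 134.5 CPM of Casp8ap2 (the other 4 libraries 92.6 to 101.5), 133.4 CPM of Plk4 (107.2 to 112.7), 229.8 CPM of Cbln1 (276.0 to 291.3) and 57.09 CPM of Enpp2 (22.4 to 30.6). WT6 stood apart at 6.93 CPM of Grin1 (4.05 to 4.77) and WT5 at 14.39 CPM of Gtse1 (18.7 to 20.1). In knockout, KO3 stood apart at 9.71 CPM of L1cam (14.6 to 15.9), KO5 at 24.07 CPM of the haemoglobin gene Hba-a2 (8.94 to 11.3) and KO2 at 4.866 CPM of the Wnt inhibitor Wif1 (1.94 to 2.52). KO8 had the largest gene count of its group, 15.08 in units of 1e+06 counts against 9.85 to 11.2, and KO2 the lowest share of records placed at several sites, 64.38% against 66.2% to 66.8%.

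The first pattern weighed is the cluster of differing genes on chromosome 8 in the 12 libraries. The GC trend is argued against by the odds ratio after the GC correction, 3.9 with a Fisher p of 1.9e-05. Neighbouring genes that vary together by chance were tested with 100 of the 462 splits of the 12 libraries into 6 and 6. In 1 of them, the real one, some autosome had as small a one-sided Fisher p (2.8e-04 on chromosome 8). The smallest one-sided Fisher p of the other splits was 3.3e-04, a narrow margin. This is under the 5% set for the test. As the test was chosen after the cluster was seen, in the fit that showed it, it cannot exclude chance. A stretch of chromosome 8 from another strain or haplotype carried by the knockout mice stays open. Chromosome 8 genes picked in the 10 libraries kept their sign between KO4 and WT2 in 9 of 61 cases (14.8%). Elsewhere 54 of 809 did (6.67%, Fisher's exact p = 0.0345). After the GC correction it was 12 of 49 (24.5%) against 101 of 570 (17.7%, Fisher's exact p = 0.248). These signs cannot decide, since the cluster was found in the 12 libraries, which include KO4 and WT2. They also rest on 1 library per group, and most chromosome 8 genes changed sign there. An effect of SnoN on these genes stays open as well, untested, and no sequence variants were analysed here.

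The second pattern is the large number of genes with an unadjusted p under 0.05, AT-rich genes higher and GC-rich genes lower in knockout. In the 10 libraries the GC correction removed only part of the excess, since 2090 genes remained under 0.05, against 2925 before and 672 at 5%. In all 12 libraries 567 of 13318 genes remained after the correction, against 666 at 5%. Genes vary together and the splits were not repeated with the correction. The remaining number thus does not show a group difference apart from the GC trend. Leaving out the marked libraries matters. Of the 36 ways to leave out 1 wild-type and 1 knockout library, the marked pair gave the most such genes, and the next pair gave 2641. Every pair with WT2 gave at least 1094, and no pair without WT2 gave more than 599. With only WT2 left out there were 1642 such genes, and with only KO4 left out 497. The number thus went mostly with leaving out WT2. Of 870 autosomal genes picked at p under 0.01 in the 10 libraries, 807 had the opposite sign between KO4 and WT2. Chance could not be excluded, as 7 of 100 splits of the 10 libraries (of 126 possible), the real one included, gave as many genes, up to 5033 against the real 2925. The split with 5033 genes set WT1, WT5, WT6, WT7 and KO5 against the other libraries. It is the real grouping with WT3 and KO5 exchanged. Its sides differ in GC trend. The named side held the highest GC slopes of the 10 libraries, 0.119 to 0.3, against -0.242 to 0.044 on the other. The log2 fold changes of this split had a Spearman correlation of -0.519 with GC content. How many of its genes remain after the GC correction was not tested.

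The third pattern is the higher Purkinje cell list in knockout. The GC trend is argued against by the list's adjusted p of 5.1e-04 after the correction (mean log2 fold change 0.32, against 0.30 before), although with an estimated correlation the list passed neither before (adjusted p = 0.974) nor after it (0.632). More Purkinje cells or their processes in the captured knockout tissue stay open. Of the 9 markers most specific to these cells 7 were measured, and all 7 had positive log2 fold changes from 0.17 to 0.61. Of these, 0 had a 95% interval that left out their median of 0.40. The intervals of Pcp2, Pcp4, Slc1a6 and Gng13 (-0.544 to 1.53) included 0, and those of Car8, Calb1 and Itpr1 did not. Intervals this wide can hardly leave out the median, and the markers belong to a cell type whose list was already seen to rise. The test thus cannot decide, and expression per Purkinje cell was not measured. As 80 of the 100 splits of the 10 libraries gave 2 or more called lists, up to 11, chance could not be excluded for the number of called lists.

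For the 3 genes that passed between the 10 libraries, 5 of the 100 splits, the real one included, gave as many or more, up to 3508. Chance could thus not be excluded for that number. The split with 3508 calls was the one with WT3 and KO5 exchanged, whose sides differ in GC slope as given above. Its calls were not counted after the GC correction.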

How the results depend on the processing

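The GC correction and the fits with only WT2 or only KO4 left out were added after the data were seen. Skil kept its direction and an unadjusted p under 0.05 in all 28 alternatives that test it, with log2 fold changes from -1.06 to -0.59 (adjusted p from 3.3e-05 to 1). Numbers of genes passing (in edgeR's test unless another is named), with the numbers higher and lower, moved from 3 (2 and 1) to 1 (1 and 0) in all 12 libraries, 965 (634 and 331) with no filter, 461 (237 and 224) by DESeq2 (adjusted p not given for 3388 genes), 2 (1 and 1) with the Y-linked covariate, 3 (1 and 2) with 1 surrogate variable, 1 (1 and 0) with only WT2 left out and 2 (1 and 1) with only KO4 left out. The GC correction gave 5 (3 and 2) in 10 libraries, 4 (2 and 2) in 12, and 3 (1 and 2) without KO2. With KO2 as wild type the number was 0 (0 and 0), with 756 genes at an unadjusted p under 0.05. With 1 library left out it ranged from 0 (without WT7 or KO2) to 3102 (without KO5), higher from 0 to 1662 and lower from 0 to 1440. RLE factors, library size alone, the stricter filter and voom in 12 libraries each gave 3.

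Called lists moved from 2 to 1 in 12 libraries (Purkinje cells), 4 with 1 surrogate variable, 7 with the GC correction (3 without KO2 and 3 in 12 libraries), and 0 with an estimated correlation or fry; it was 3 with KO2 as wild type, and 2 or 3 with 1 library left out. The 3 lists called in 12 libraries with the GC correction were Purkinje cells, the granule precursor and Shh list and maturing granule neurons. The Purkinje list was called in 27 of 28 alternatives (adjusted p 1.1e-04 to 0.0765) and the mitochondrial list in 24 of 28 (9.2e-06 to 0.297). The list of early differentiating granule neurons turned from a mean of 0.03 to -0.09 (adjusted p = 0.0328) with 1 surrogate variable; the causes of these changes were not tested.

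The numbers in the titles showed no pairing in the 10 libraries (correlations of deviations 0.11, -0.05 and 0.09 for numbers 3, 5 and 6, and no library correlated best with its own number). In all 12, numbers 2, 3, 5 and 6 gave 0.328, -0.047, 0.134 and 0.042, and WT2 was the best match of KO2, but KO3 that of WT2. Pairing was thus not shown. The counts with the replicate block are given here alone, though ranges over all alternative settings include these fits. Only numbers 3, 5 and 6 occur in both groups of the 10 libraries, and 2, 3, 5 and 6 in all 12. With the block only these libraries inform the group difference, so a loss of calls does not show an effect of pairing. With the block, 0 genes passed (0 higher, 0 lower; 607 at an unadjusted p under 0.05) and 5 lists were called, in 12 libraries 0 genes (0 and 0; 147) and 0 lists, and with block and GC correction 0 genes (0 and 0; 569) and 5 lists; Skil had -0.82, -0.89 and -0.99.

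Depth did not prevent calls at this size in simulated data, but 1.5-fold changes were recovered in 46.3% of cases, so smaller changes may be missed. The simulated genes were drawn independently, so the simulated recovery rates need not hold for the real libraries. In the real fit of 10 libraries some larger changes did not pass either. Pigb (log2 fold change -1.34) and Adcy8 (-2.02) each had an adjusted p of 0.124 in edgeR's quasi-likelihood test.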

Other observations

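Full separation of 6 knockout from 6 wild-type libraries was counted after the results above were seen, as a view that leaves out no library. Of 13318 genes, 20 were fully separated, 11 higher and 9 lower in knockout, where chance gives 0.216% of genes, or 28.8. They included Skil, fixed beforehand, and Trmt9b, Fut10 and the adenylyl cyclase Adcy8 (log2 fold change -1.74 in 12 libraries), picked by the rule from their p. Also among them were Nek3, Mau2, cytochrome c, Cycs (0.53), the receptor phosphatase Ptprm (0.85) and Tnfaip8l3 (-1.14), named after their values were seen.

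X-linked Xist was at 104 to 196 CPM in WT1, WT3, WT6, KO2, KO4 and KO6, in which 4 Y-linked genes summed to at most 1.34 CPM. In WT2, WT5, WT7, KO3, KO5 and KO8 the Y-linked sum was 308 to 635 CPM and Xist at most 9.36 CPM. Over all 12 libraries both groups thus held 3 libraries of each kind. The comparison without WT2 and KO4 was not balanced in this way. There WT1, WT3 and WT6 had high Xist and WT5 and WT7 high Y-linked sums. In knockout KO2 and KO6 had high Xist and KO3, KO5 and KO8 high Y-linked sums. The first principal component of the 12 libraries carried 27.8% of the variance of the 1000 most variable genes, with WT2 (29.4) and KO4 (-28.0) at its ends.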
